A study of Mus musculus with 9 samples.

How the data were processed

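WT1 binding was measured by chromatin immunoprecipitation with sequencing (ChIP-seq) in kidney cortex of CD-1 mice, and RNA was sequenced from podocytes isolated by fluorescence-activated cell sorting. Of the 9 samples, 3 were immunoprecipitated with an antibody against WT1 and 3 were input DNA, all from mice of 3 weeks. The other 3 were podocyte RNA from mice of 6 weeks that carried a Nphs2-driven Cre recombinase and the R26mTmG reporter, which switches from a red to a green membrane protein in cells with Cre activity. Samples were grouped by their titles and source names. The labels number the samples of each group as replicates without stating whether they came from separate animals, so spreads between them may be partly technical.

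The RNA values are FPKM, fragments mapped to a gene scaled by transcript length and by the total of mapped fragments, as deposited by the authors in 2 tables. Replicates 1 and 2 stand side by side in a table keyed by gene symbol, and replicate 3 stands in a table keyed by Ensembl gene identifier with a symbol. TopHat2 2.0.10 and build mm9 are named for every sample, per the submitters' processing notes, without a stated role. The program that computed FPKM and the gene annotation are not given in the sources used here. The tables were normalized separately, so values of replicate 3 are set beside those of replicates 1 and 2 with that limit, and percentiles across the tables describe these 3 libraries only. The peak score was deposited by the authors in 1 list for the ChIP samples against the input samples, made with spp under a conservative setting, per the file headers and the labels. The scale and threshold of the score are not given in the sources used here, and the list carries no value per replicate. The score is therefore used only to rank and filter peaks within the list.

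The first table held 23307 symbols and the second 38222, of which 21947 were in both and were analysed. A symbol on several lines took its highest value. In all, 25 symbols had been turned into dates, as spreadsheets do, and were not matched. The gene table of GRCm38.p6 was used for older symbols and, in 1 test, for gene spans. No counts accompany the FPKM, so the depth of the libraries is unknown and no counting interval is given. Among 2891 genes under 0.3 FPKM in both replicates 1 and 2, the most frequent ratio of replicate 2 to replicate 1 was 1.07, held by 329 genes within 0.02 on the log2 scale. For replicate 3 it was 0.409 over replicate 1 (83 of 2805 genes) and 0.774 over replicate 2 (74 of 2661 genes). These 3 ratios contradict each other, so no relative depth of replicate 3 is given. An exact 0 can be a failed estimate in these tables, since Ubc, a ubiquitin gene used by every cell and chosen after its values were seen, is listed at 0, 0 and 206 FPKM in replicates 1, 2 and 3.

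Means and standard deviations (SD) were taken over the 3 podocyte samples. For a gene list, the median over its members was taken in each sample, and the mean ± SD of these 3 medians is given. A gene was counted as detected at 1 FPKM or more. Before the data were examined, 19 gene lists were fixed, covering podocyte functions, other cell types and reference processes. The rule for named genes was fixed with them and allows at most 6 members per list, those with the highest mean FPKM, and Wt1. Other genes are said to have been chosen after their values were seen.

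With a single RNA group, no test between conditions was possible. The tests below were chosen after the files were seen, because the planned tests could not be run. The level of each list, the median of the mean log2(FPKM + 0.1), was compared with 10000 random lists of the same size from the 21947 genes. This permutes list membership among genes. Those tests were two-sided, with Benjamini-Hochberg adjustment over the 19 lists. The median of podocyte genes was compared with that of marker genes of other kidney cell types by a two-sided permutation test with 100000 permutations of the gene labels. Fold changes are on the log2(FPKM + 0.1) scale, which understates those of low genes. Genes are not independent replicates, so these p-values describe the lists within these samples. Differences between replicates were placed among 10000 random lists matched on mean expression in 40 bins. Peaks were placed at random 10000 times between the first and last peak of their chromosome, and the share with another peak within 10 kb was compared, two-sided. That placement takes no account of assembly gaps or regions where reads cannot be mapped. Peak density on chromosome X was compared with the autosomes by an exact binomial test. The correlation of score with the distance to the nearest peak was tested across peaks by a permutation test with scores permuted within chromosomes.

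On simulated data, random lists of 20 genes without a shift passed the 0.05 threshold in 7.5% of draws over 21947 genes. Lists shifted by 4 log2 units passed in 65.5% and lists shifted by 8 in 100%. The larger shift was added after the smaller one had been recovered incompletely, so a list moderately above chance can be missed by this test. Matched lists over 10450 genes passed in 6% of draws without a shift and in 100% with a shift of 1 log2 unit. That simulation used independent noise unrelated to expression, in 20 bins of expressed genes, against 40 bins over 21947 genes in the data. It therefore does not give the error rate for lists of genes that vary together. The permutation test of medians, on 100 genes, passed in 1% and 100% of draws without and with a shift. Simulated uniform and planted clustered peaks, 14843 each, gave ratios of 1.00 and 3.72 to random placement.

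The peak coordinates are those of mm9, per the submitters' processing notes. As a check, 124 peaks on 6 chromosomes lay beyond the last gene of GRCm38, so no gene positions of that assembly were used with them. For this reason the planned analyses that join peaks to genes were not run. These were peak location relative to genes, expression of bound against unbound genes, the share of bound genes by expression class, peak strength and expression, peaks per gene, binding of the gene lists and the WT1 motif in peaks. Alternatives tried were other pseudocounts of 1 and 0.01 FPKM, a filter at a mean of 1 FPKM, leaving out each replicate, medians over replicates, summing lines of one symbol, stronger peaks only, merging of peaks under 1 kb apart, a distance of 50 kb, and placement within 500 kb. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.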

Results

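The study examined where the transcription factor WT1 binds in the mouse kidney and which genes podocytes express. WT1 is a zinc finger protein that in the mature kidney is found chiefly in podocytes, the epithelial cells whose interlocking foot processes and slit diaphragms form the outer layer of the glomerular filter. The data comprised 1 list of WT1 peaks, called over 3 ChIP samples and 3 input samples of kidney cortex, and gene expression in FPKM for 3 samples of sorted podocytes. In replicates 1, 2 and 3 the FPKM summed to 454992, 478161 and 465892, and 10652, 10387 and 11585 symbols reached 1 FPKM. Of the 21947 symbols in both tables, 9639 (43.9%) reached 1 FPKM in all 3 replicates and 453 reached 100 FPKM in all 3. Sequencing depth was unknown.

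Replicates 1 and 2 resembled each other more closely than either resembled replicate 3, which came from a separately normalized table. Over the 10450 genes with a mean of 1 FPKM or more, the correlation across genes of log2 values was r = 0.895 and rho = 0.951 between replicates 1 and 2. It was r = 0.718 and rho = 0.832 between replicates 1 and 3, and r = 0.794 and rho = 0.853 between replicates 2 and 3. A difference of at least 2-fold separated replicates 1 and 2 at 312 genes (2.99%), against 20.9% of genes between replicates 1 and 3 and 23.5% between replicates 2 and 3.

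Genes of the slit diaphragm and foot process were among the most abundant transcripts of the sorted cells. Nphs2, which encodes the slit diaphragm protein podocin, stood at 4615 ± 1193 FPKM (SD, n = 3). Podxl, encoding the surface sialoprotein podocalyxin, stood at 4332 ± 1111 FPKM (SD, n = 3). Nphs1 (nephrin) followed with 1134 ± 265 FPKM, Synpo (the actin-associated synaptopodin) with 1123 ± 329 FPKM, Cdkn1c (a cyclin-dependent kinase inhibitor) with 1641 ± 55.8 FPKM and Enpep (aminopeptidase A) with 1192 ± 135 FPKM (SD, n = 3 each). Of the 34 members of this list 32 reached 1 FPKM in every replicate, and 18 reached 100 FPKM. The exceptions, chosen after their values were seen, were Trpc6, a cation channel gene, and Kirrel3, a nephrin-like adhesion gene. The list median was 184, 167 and 179 FPKM in replicates 1, 2 and 3, a mean of 177 ± 8.37 FPKM. It lay above all 10000 random lists (random-list permutation test, adjusted p = 2.4e-04, where p was 1e-04, the smallest these draws can give).

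Wt1 itself was expressed at 497 ± 53.7 FPKM (SD, n = 3), the highest level in the list of podocyte transcription factors. Tcf21 (348 ± 19.0 FPKM), Mafb (318 ± 22.5 FPKM), Lmx1b (119 ± 8.20 FPKM) and Dach1 (86.3 ± 12.3 FPKM) differed little between the replicates (SD, n = 3 each). Klf6, a zinc finger factor gene, instead stood at 270 and 281 FPKM in replicates 1 and 2 and at 27.3 FPKM in replicate 3. In all, 13 of the 16 factors measured in both tables reached 1 FPKM in every replicate, and Pax2, Osr2 and Hey1, chosen after their values were seen, did not. The list median was 43.5 ± 6.38 FPKM (random-list permutation test, adjusted p = 2.4e-04).

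The glomerular basement membrane and adhesion list had a median of 87.2 ± 12.4 FPKM, with 19 of 24 genes at 1 FPKM or more in every replicate. Itgb5 (749 ± 42.5 FPKM), Itgb1 (436 ± 93.0 FPKM) and Itga3 (351 ± 17.5 FPKM), which encode integrin chains, and Npnt (679 ± 117 FPKM), which encodes the matrix protein nephronectin, were the most abundant members together with Cd151 and Col4a3 (SD, n = 3 each). Col4a3, a collagen chain of the mature glomerular basement membrane, stood at 398 ± 93.1 FPKM. The genes of the chains Col4a1 and Col4a2 of other basement membranes were each under 1 FPKM in at least 1 replicate, as were Lamb1, Nid1 and Hspg2 (all 5 chosen after their values were seen). Genes of hereditary nephrotic syndrome, a group of inherited protein-losing kidney diseases, had a median of 48.8 ± 2.25 FPKM with 37 of 44 at 1 FPKM or more in every replicate. Besides Nphs2, Nphs1 and Wt1, the most abundant were Actn4 (563 ± 59.9 FPKM), an actin cross-linking protein gene, and Ptpro (432 ± 98.7 FPKM), a receptor phosphatase gene. Actin regulators had a median of 82.2 ± 7.03 FPKM (29 of 30 genes detected in every replicate), including Cfl1 at 632 ± 344 FPKM and Arpc2 at 274 ± 9.56 FPKM. Genes of the Hippo pathway, a kinase cascade that restrains the coactivators YAP1 and TAZ, had a median of 20.4 ± 5.31 FPKM (20 of 23 detected). Their most abundant member Cyr61 was at 1287, 1811 and 31.5 FPKM in the 3 replicates, while Amotl2 (139 ± 8.95 FPKM) and Yap1 (57.2 ± 7.29 FPKM) were close in all 3. All of these lists lay above the random lists (random-list permutation tests, adjusted p = 2.4e-04 each), as did housekeeping genes with a median of 112 ± 11.8 FPKM. Many of the genes drawn lie near 0, so a list of expressed genes passes readily, and some lists share members such as Actn4 and Col4a3. Against genes with a mean of 1 FPKM or more, Hippo genes stood 1.18 log2 units above random (same permutation test, adjusted p = 0.0317). There, basement membrane, nephrotic syndrome and actin lists stood 3.21, 3.07 and 3.02 above, and housekeeping genes 3.20 (permutation test, adjusted p = 2.4e-04 each).

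Secreted and guidance factors ranged from very high to near-absent genes. Sema3g, a semaphorin gene, stood at 3291 ± 1089 FPKM, Sparc at 1311 ± 123 FPKM, and Vegfa, encoding the main growth factor for the adjoining endothelium, at 1222 ± 85.6 FPKM (SD, n = 3 each). Only 11 of the 20 members reached 1 FPKM in every replicate, and the list did not pass the test (13.9 ± 17.1 FPKM, random-list permutation test, adjusted p = 0.133). Its median depended on replicate 3, without which it was 4.03 FPKM, and among genes with a mean of 1 FPKM or more its 11 members did pass, 3.44 log2 units above the random median (same permutation test, adjusted p = 2.4e-04). WT1 targets reported before this study did not pass as a list (2.84 ± 1.66 FPKM, random-list permutation test, adjusted p = 0.497). The list did not separate its members by the direction or the tissue of the reported regulation. A low level of this list therefore does not tell whether WT1 regulates its members in podocytes. Without replicate 3 the median of these targets was 1.88 FPKM. Only 12 of their 22 members reached 1 FPKM in every replicate, among them Nphs2, Podxl, Nphs1, Nes (449 ± 19.6 FPKM), Sulf1 (75.3 ± 7.12 FPKM) and Igf1r (16.5 ± 3.16 FPKM).

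**Figure D1:**
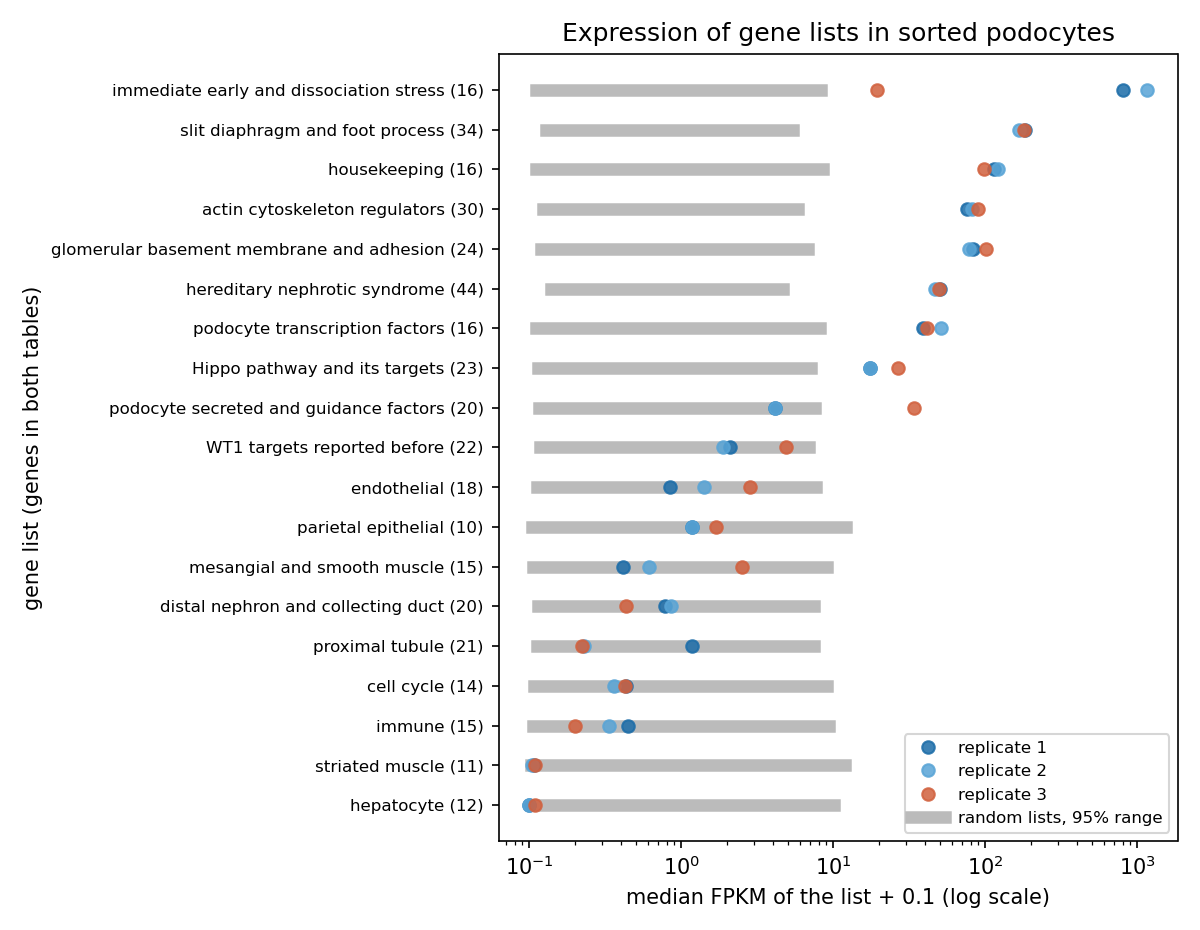
Median FPKM plus 0.1 (x axis, log scale) of each gene list (y axis, with the number of genes in both tables) in podocyte replicates 1, 2 and 3 (points), with the central 95% range of 10000 random lists of the same size (gray bars). The slit diaphragm list lies at 184, 167 and 179 FPKM, far right of its bar, and the lists of the 6 other kidney cell types lie within theirs.

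Podocyte genes were compared with markers of other kidney cell types to describe the sorted RNA. The 49 genes of the slit diaphragm and transcription factor lists had a median of 112 FPKM, and 45 of them (91.8%) reached 1 FPKM in every replicate. The 98 markers of endothelial, mesangial, proximal tubule, distal nephron, parietal epithelial and immune cells had a median of 0.803 FPKM, and 21 of them (21.4%) reached 1 FPKM in every replicate. Pax2 stood in both sets and was left out. The medians of the mean log2(FPKM + 0.1) differed by 7.39 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Both sets were listed for the cells that express them, so any podocyte-enriched RNA would give a low p, which does not measure purity. Only the slit diaphragm and transcription factor lists were pooled as podocyte genes, without the secreted factors and other podocyte lists. In replicates 1, 2 and 3 taken singly the difference was 7.19, 7.33 and 7.91. By cell type it ranged from 6.19 against endothelial markers to 8.37 against immune markers, and the largest adjusted p, 0.00148, was that against parietal epithelial markers.

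Among the other cell types, Cldn5, a tight junction gene of the endothelial list, was the exception, with 438 ± 25.1 FPKM (SD, n = 3). The endothelial genes Ehd3, Emcn, Eng, Egfl7 and Kdr stood far lower and were higher in replicate 3, for example Emcn at 3.11, 5.44 and 13.5 FPKM and Eng at 1.15, 2.42 and 9.60 FPKM in replicates 1, 2 and 3. The endothelial list median was 1.60 ± 1.03 FPKM, and 1.03 FPKM without replicate 3. Mesangial and smooth muscle genes had a median of 1.07 ± 1.15 FPKM, and 0.409 FPKM without replicate 3, led by Tagln at 23.6 ± 13.4 FPKM and Pdgfrb at 12.7 ± 3.74 FPKM. Proximal tubule genes had a median of 0.445 ± 0.553 FPKM, and 0.126 FPKM without replicate 1, where Kap, an androgen-regulated tubule gene, stood at 86.8 FPKM against 6.90 and 0.567 FPKM in replicates 2 and 3. In the distal nephron list (0.588 ± 0.222 FPKM) Egf was at 58.7, 57.7 and 135 FPKM and Umod, encoding uromodulin, at 25.4 ± 7.69 FPKM. Parietal epithelial genes had a median of 1.24 ± 0.297 FPKM, led by Aldh1a2 at 24.4 ± 10.7 FPKM, and immune genes 0.227 ± 0.125 FPKM, led by Csf1r at 4.27 ± 2.81 FPKM. Cell cycle genes had a median of 0.307 ± 0.0396 FPKM, with Pcna, a DNA replication clamp gene, as the one abundant member at 51.0 ± 21.1 FPKM. No gene of the hepatocyte list or the striated muscle list in both tables reached 1 FPKM in every replicate. Acta1, a skeletal muscle actin gene chosen after its values were seen, stood at 35.2 and 0.124 FPKM in replicates 1 and 2 and was not matched in the table of replicate 3.

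None of these lists passed the test against random lists drawn from all genes (random-list permutation tests, adjusted p from 0.359 for hepatocyte to 0.986 for distal nephron genes), a test with little room below, since many genes of the tables lie near 0. The hepatocyte list lay at percentile 2.39 of its random lists. Against genes with a mean of 1 FPKM or more, the 13 endothelial genes of that level stood at -2.49 log2 units from the random median (permutation test as before, adjusted p = 9.4e-04). The 8 mesangial genes stood at -1.89 (same permutation test, adjusted p = 0.0308) and the 7 distal nephron genes at -1.91 (adjusted p = 0.0445). Proximal tubule genes (-1.49, adjusted p = 0.161), parietal epithelial genes (-1.68, adjusted p = 0.110), immune genes (-2.16, adjusted p = 0.0539) and cell cycle genes (-2.59, adjusted p = 0.0619) did not pass this permutation test.

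Immediate early and stress genes, which cells switch on within minutes of a stimulus, had the highest median of all lists and the widest spread. It was 810 and 1152 FPKM in replicates 1 and 2 and 19.2 FPKM in replicate 3, a mean of 660 ± 581 FPKM that was 415 FPKM without replicate 2 and 981 FPKM without replicate 3. All 16 members reached 1 FPKM in every replicate (random-list permutation test, adjusted p = 2.4e-04). Fos stood at 3173, 4310 and 22.2 FPKM, Fosb at 2134, 2759 and 6.21 FPKM, Jun at 1521, 2291 and 89.7 FPKM and Atf3 at 1379, 1634 and 5.45 FPKM in replicates 1, 2 and 3. Nr4a1 stood at 1602, 2646 and 16.1 FPKM and Junb at 1127, 1820 and 11.6 FPKM. In 14 of the 16 genes the mean of replicates 1 and 2 was over 10 times the value of replicate 3. The other 2, chosen after their values were seen, were the heat shock genes Hspa1a (20.7, 121 and 60.1 FPKM) and Hspa1b (17.4, 121 and 97.5 FPKM). Klf6 and Cyr61 showed the same order of replicates as this list. The comparison lies across the separately normalized tables, and replicate 3 is a single sample.

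**Figure D2:**
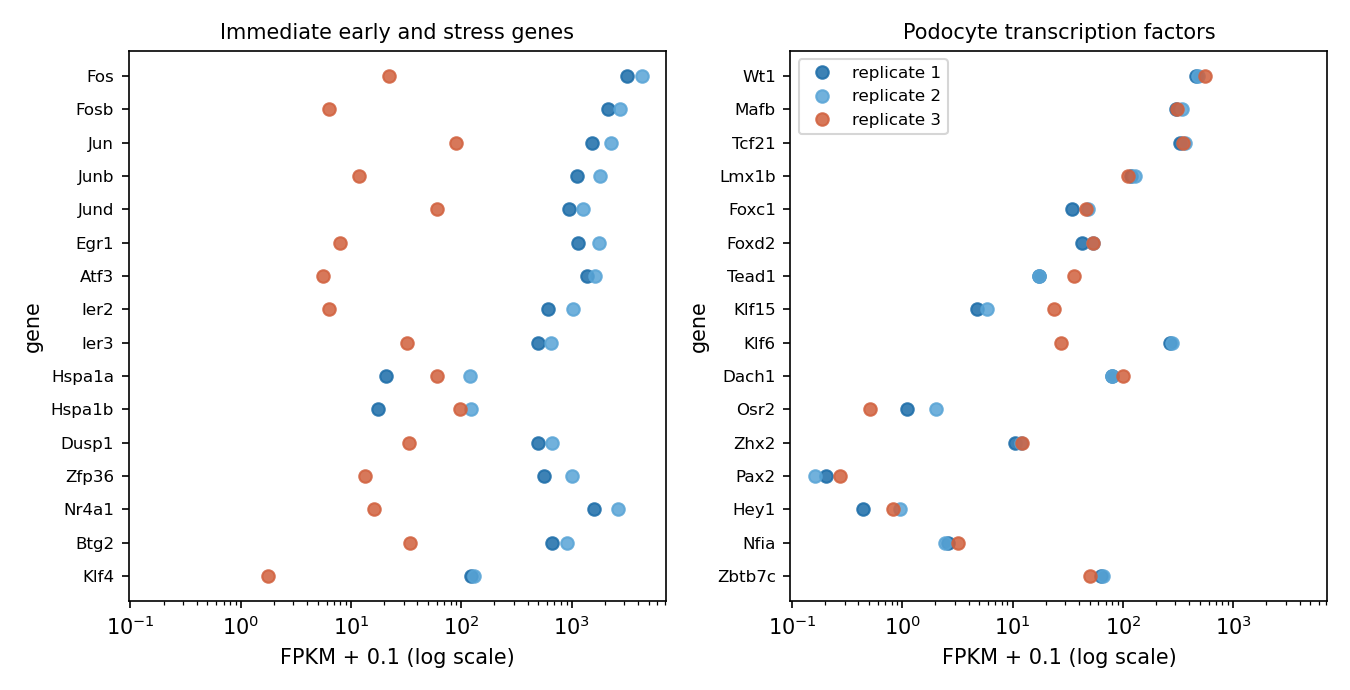
FPKM plus 0.1 (x axis, log scale) of each immediate early and stress gene (left) and each podocyte transcription factor (right) in podocyte replicates 1, 2 and 3 (points). Fos is at 3173 and 4310 FPKM in replicates 1 and 2 and at 22.2 FPKM in replicate 3, while Wt1 is at 457, 477 and 558 FPKM.

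WT1 peaks were mapped to ask where the factor binds in kidney cortex chromatin. The list held 14843 peaks on the 19 autosomes and chromosome X, with 0 on chromosome Y, and their lengths summed to 4092657 bp. The authors' score ran from 39.0 to 726 with a median of 71.7, and 495 peaks (3.33%) scored 300 or more. The strongest peak lay on chromosome 9 from 108999450 to 108999808 (score 726, coordinates of mm9 throughout). It was followed by peaks on chromosome 10 from 121392903 to 121393236 (score 615), on chromosome 9 from 102619852 to 102620168 (score 613), on chromosome 11 from 97530639 to 97530943 (score 607) and on chromosome 11 from 105153700 to 105154080 (score 587). Gene positions of mm9 were not used here, so the genes at these sites are not named. A width of 316 bp was shared by 10320 peaks (69.5%), and this share went from 99.6% of the 2969 lowest-scoring peaks to 0.505% of the 2969 highest-scoring ones.

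Peaks lay close together along the chromosomes. Another peak stood within 10 kb of 45.0% of peaks, against 11.9% on average and at most 13.5% under random placement, a ratio of 3.78 (n = 14843 peaks, p = 1e-04, the smallest that 10000 placements can give). Peaks linked by gaps of up to 50 kb formed 6580 groups. Of these, 3600 were single peaks (24.3% of all peaks), and 148 groups of 10 or more held 1988 peaks (13.4%). The largest group held 30 peaks on chromosome 19 from 46522459 to 46802972, the next 29 peaks on chromosome 4 from 128710790 to 129083990, and the next 28 peaks on chromosome 8 from 73030171 to 73430615. Stronger peaks had nearer neighbours. A neighbour within 10 kb stood beside 39.3% of the 2969 lowest-scoring peaks and 55.3% of the 2969 highest-scoring peaks, and score and distance to the nearest peak correlated with rho = -0.13 across peaks (permutation test, p = 1e-05). Placement of each peak within 500 kb of its own position brought the ratio to 2.02. A neighbour distance of 50 kb brought it to 1.63 (75.7% of peaks against 46.3% at random). The 1485 strongest peaks, taken alone, gave 12.0, with a neighbour within 10 kb beside 16.2% of them against 1.34% at random. With fewer peaks placed the random share is low, so 12.0 is not comparable with 3.78. Among those 1485 peaks the correlation was -0.06 (same permutation test, p = 0.0351). This test of the correlation takes the peaks of a chromosome as independent, which grouped peaks are not, so its p-values may be too small.

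Chromosome X carried few peaks. Its density was 1.53 per Mb between its first and last peak, against 6.12 per Mb over the autosomes, a ratio of 0.250 (exact binomial test, p = 3.4e-164). Every autosome had a higher density, from 4.52 per Mb on chromosome 14 to 10.5 per Mb on chromosome 11, and chromosomes 19 (9.26 per Mb) and 17 (8.52 per Mb) followed chromosome 11. The binomial test takes peaks as independent, which grouped peaks are not, so its p is too small. Among the 1485 strongest peaks the ratio was 0.151. The sex of the animals is not given in the sources used here.

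**Figure D3:**
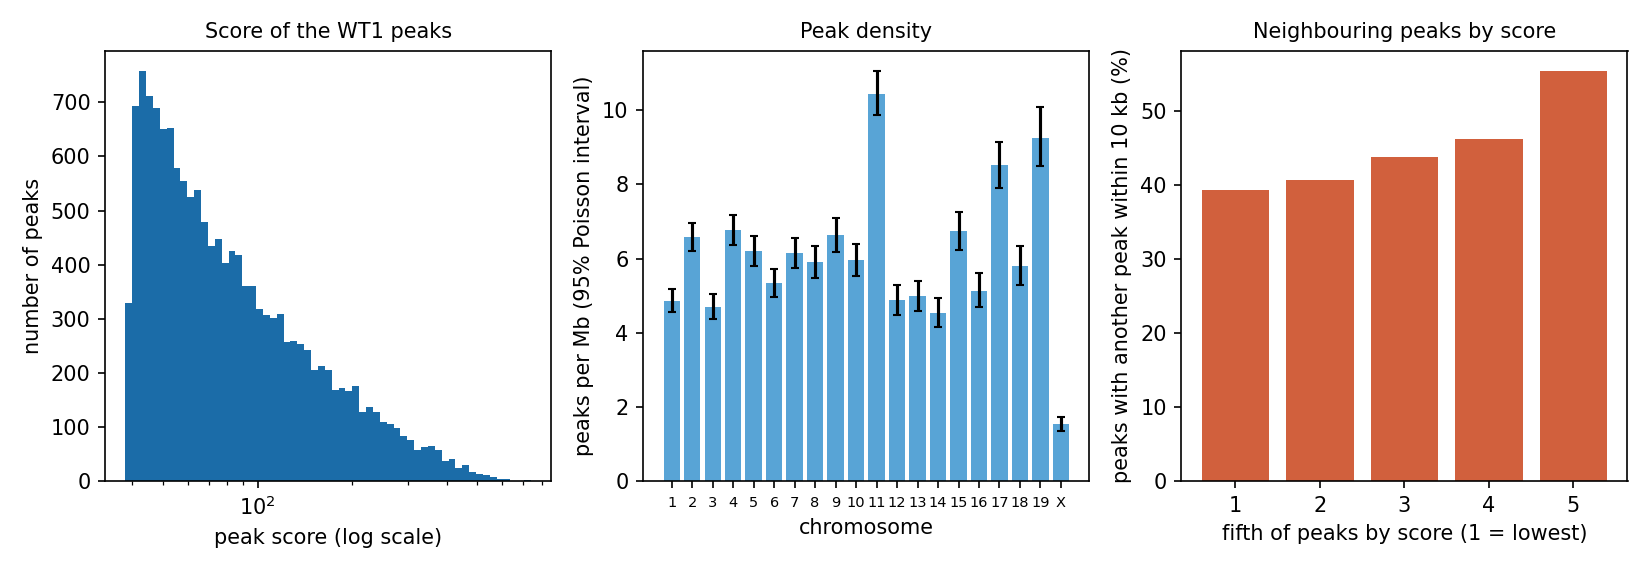
Number of WT1 peaks by score (left, log scale), peaks per Mb of each chromosome with 95% Poisson intervals (middle) and percent of peaks with another peak within 10 kb in 5 equal classes of rising score (right). Chromosome X has 1.53 peaks per Mb against 4.52 or more on every autosome, and the percent with a neighbour goes from 39.3 in the lowest class to 55.3 in the highest.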

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

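All alternatives except leaving out a replicate and taking the median over replicates for the list medians were chosen after seeing the data. Of 246 alternatives over 42 results, 234 kept their direction and their side of the threshold, or for list medians moved by less than 1 SD over the replicates. For list medians that bound could not be passed by leaving out a replicate or by taking the median over replicates. The mean of 3 values never moves by 1 SD of those same values under either change. These labels therefore say nothing about stability. Where a list has a wide SD, its values without the deciding replicate stand in the report. The list median was itself redefined after the outcome of its alternatives had been seen. It was first the median over genes of each gene's mean FPKM, and by that quantity 10 of 95 alternatives in 6 lists moved by over 1 SD, among them hereditary nephrotic syndrome from 56.2 to 48.4 FPKM, Hippo genes from 23.7 to 17.4 FPKM and actin regulators from 87.9 to 78.4 FPKM, each without replicate 3, and housekeeping genes from 109 to 123 FPKM without replicate 1. By that quantity hereditary nephrotic syndrome stood at 56.2 FPKM and striated muscle at 0.0109 FPKM, against 48.8 ± 2.25 and 0.00694 ± 0.00248 FPKM in the quantity reported. Against genes with a mean of 1 FPKM or more only, log2 distances from random lists turned to -2.49 (endothelial), -1.89 (mesangial), -1.91 (distal nephron) and -1.68 (parietal epithelial), and secreted factors came to pass at 3.44. The background there excludes low genes by construction. Hepatocyte and striated muscle lists gave no value under that filter, having under 3 genes left. Against all genes, distances that did not pass changed sign in other settings. Leaving out each replicate gave -0.46 to 1.23 for mesangial, -1.57 to 0.020 for proximal tubule and -0.20 to 0.39 for distal nephron genes, and a pseudocount of 1 FPKM gave -0.0757 for the last. The cause was not tested. The podocyte difference of 7.39 ranged from 5.34 to 8.15 and passed under all 9 alternatives. Clustering ratios ranged from 1.63 to 12.0 and the chromosome X ratio from 0.151 to 0.251. The ratio of 12.0, among the 1485 strongest peaks, rests on a low random share. No paired analysis was possible because no test compared groups that share replicate numbers. Other settings listed beforehand for peak location, bound genes, expression classes, peak strength, peaks per gene, list binding and the WT1 motif were not run. Unknown depth leaves the precision of low FPKM values open.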

Other observations

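Every gene in this paragraph was chosen after its values were seen. Among the 21947 symbols in both tables, which leave out the mitochondrial ones, the highest mean was that of Tmsb4x, encoding the actin-binding peptide thymosin beta 4, at 6275 ± 1994 FPKM (SD, n = 3). Igfbp7, encoding a secreted binding protein, stood at 4118 ± 776 FPKM and Itm2b, encoding a membrane protein, at 3833 ± 668 FPKM. Plat, encoding tissue plasminogen activator, stood at 1589 ± 84.1 FPKM, and Vim, encoding the intermediate filament protein vimentin, at 2651, 3466 and 718 FPKM in replicates 1, 2 and 3. Xist, the long RNA of the inactive X chromosome, stood at 0.0418, 0.0476 and 69.7 FPKM in replicates 1, 2 and 3. The Y-linked genes Ddx3y (20.9 ± 3.70 FPKM) and Eif2s3y (22.9 ± 1.43 FPKM) were present in all 3. Prm1, a sperm protamine gene, was listed at 0, 0 and 151 FPKM.

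Among 688 microRNA and small nucleolar or Cajal body RNA genes, 32 were listed at 0 in one of replicates 1 and 2 and at 100 FPKM or more in the other. Only 1 of 21259 other symbols did so, Actr3 (chosen after its values were seen), at 0 FPKM in replicate 1 and 128 FPKM in replicate 2. The table of replicate 3 also held 37 mitochondrial symbols that the other table lacked, with 6.33% of its FPKM total.

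Of the tests that follow, those of scale, gene span, immune RNA, handling and pieces of sites were chosen after the result they measure was seen, and those on second gene lists and on regional density before. Immediate early genes were lower in replicate 3 than in replicates 1 and 2 by a median of 5.99 on the log2 scale. A scale difference between the tables is argued against by the median expressed gene, which shifted by -0.0831. A bias by gene span is argued against by 10000 lists matched on expression and gene span, which reached at most 1.78. Gene span is not the transcript length that scales FPKM, so that test cannot decide on a bias of short transcripts. RNA of immune cells is argued against by the most abundant immune marker, Csf1r, which reached only 6.71 FPKM in replicates 1 and 2. A second list of 34 early genes, written before its values were seen, was higher in all 34 by a median of 3.63, so the difference may be a broad early response. Handling of cells, treatment, a share of female animals and separate processing cannot be told apart here, since 0 tables hold both kinds of sample. Xist stood at 0.0418, 0.0476 and 69.7 FPKM in replicates 1, 2 and 3. The Y-linked genes Ddx3y (23.0, 23.1 and 16.6 FPKM) and Eif2s3y (22.3, 24.5 and 21.8 FPKM) stayed close in all 3. Replicate 3 therefore held RNA of male cells, which argues against a contrast of males alone with females alone. The columns of replicates 1 and 2 share the name Ctrlinj, whose meaning is not given in the sources used here.

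Proximal tubule genes were higher in replicate 1 than in replicate 2 in 20 of 21 genes, by a median of 1.87 on the log2 scale. The median expressed gene differed by 0.0254, which argues against scale. The 25 further endothelial genes differed by -0.42, the opposite direction, which argues against an equal rise of all other cell types. Immune (11 of 15), parietal epithelial (7 of 10) and distal nephron genes (15 of 20) were also higher in replicate 1. Their differences, replicate 2 minus 1, lay at percentiles 4.19, 9.1 and 16.96 of matched lists. A lower share of podocytes in replicate 1 therefore remains undecided. RNA of proximal tubule cells in replicate 1, which the sort should remove, could account for the pattern but remains open. A second list of 29 tubule genes was higher in 25 genes, by a median of 0.87, beyond all 10000 matched lists but short of the bound of 1 set beforehand. Kap stood at 86.8 against 6.90 FPKM, Miox at 4.29 against 0.137 FPKM and Slc34a1 at 2.51 against 0.130 FPKM in replicates 1 and 2.

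Peaks lay closer together than random placement gave, with a ratio of 3.78. Sites called in several pieces are argued against as the whole cause, since merging peaks under 1 kb apart left a ratio of 3.21. Regional density over 500 kb may account for part of the pattern, since placement within 500 kb lowered the ratio to 2.02, but not for all of it. With both changes together the ratio was 1.74. No biological explanation was tested, since the genes at these sites were not analysed here.

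Between replicates 1 and 2, which share a table, immediate early genes were 1.43-fold higher in replicate 2 in 16 of 16 genes and endothelial genes 1.76-fold higher in 17 of 18, both beyond all 10000 matched lists. Mesangial genes lay at percentile 99.42 with a median log2 shift of 0.263, but 8 were higher and 7 lower in replicate 2. Slit diaphragm genes, lower in replicate 2 in 27 of 34, lay at percentile 0.1, but their median log2 shift was only -0.108. Hippo genes, lower in 18 of 23, lay at percentile 1.72 with a median log2 shift of -0.138. Across the separately normalized tables, endothelial genes were 3.17-fold higher in replicate 3 than in the mean of replicates 1 and 2 in 17 of 18 genes (percentile 0), and 2.61-fold higher than in replicate 2 alone (percentile 0.02). Mesangial genes were 4.63-fold higher in 12 of 15 (percentile 0). Several podocyte lists were also higher in replicate 3 by smaller folds. Slit diaphragm genes were 1.26-fold higher in 23 of 34 (percentile 0) and basement membrane genes 1.37-fold in 19 of 24 (percentile 0.02). Hereditary nephrotic syndrome genes were 1.22-fold higher in 29 of 44 (percentile 0.08) and Hippo genes 1.37-fold in 19 of 23 (percentile 0.39). Secreted factors were 1.23-fold higher in 12 of 20 (percentile 0.68). Podocyte transcription factors lay at percentile 7.93, and actin regulators, only 1.03-fold higher in 17 of 30, at percentile 5.55. Other lists went the opposite way, with distal nephron genes 1.99-fold lower in replicate 3 in 17 of 20 genes (percentile 99.97) and immune genes 1.68-fold lower in 13 of 15 (percentile 99.94). Egf of the distal nephron list was instead higher in replicate 3. These folds rest largely on low values, since only 4 of 20 distal nephron and 2 of 15 immune genes reached 1 FPKM in every replicate. The same holds for endothelial (5 of 18) and mesangial genes (4 of 15). Proximal tubule genes were 2.25-fold lower in 18 of 21 (percentile 99.99), which rested on replicate 1, since against replicate 2 alone they were 1.15-fold lower in 14 of 21 (percentile 94.18). Parietal epithelial genes were 1.59-fold higher in 7 of 10 (percentile 7.79). Each percentile is that of the difference, replicate 2 minus 1 within the table and replicate 3 subtracted across tables, among 10000 lists matched on mean expression.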
